A study of Anopheles stephensi with 4 samples.

How the data were processed

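RNA from 4 tissues of adult female Anopheles stephensi, a mosquito that transmits malaria in South Asia, was measured by paired-end RNA sequencing. The tissues were fat body, ovary, midgut and Malpighian tubules, and each was represented by 1 library. Per the labels' protocols, the females were sugar fed and kept at 27 °C and 70% humidity with 12 h of light and 12 h of darkness, total RNA was extracted with a miRNeasy kit, and indexed libraries were made with a TruSeq RNA kit. Each library was run on 2 lanes as technical replicates, per the labels. The lanes measure sequencing error and not the spread between mosquitoes, so no difference between tissues has a replicate check and no p-value is given.

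Per the submitters' processing notes, the tools were CASAVA 1.8, HISAT2, StringTie 1.2.1 and Cuffdiff, and the versions of HISAT2 and Cuffdiff were not given there. The genome build was not given in the sources used here. Coordinates are 1-based and stand on the scaffolds named in the deposited transcript annotation. The deposited FPKM values (fragments per kilobase of transcript, scaled for library size) were given by the authors for 25785 transcripts in each tissue, with a lower and an upper bound and a status, per the file headers. The 25794 transcripts of the annotation included 9 without values. The authors also deposited 3 lists of FPKM values, of 9722 annotated, 8820 alternative and 2694 intergenic transcripts. These lists held the transcripts of their class with at least 0.1 FPKM in any tissue. Their values matched the FPKM table within 0.1% or 0.001 FPKM, apart from 5 isoforms of 1 gene.

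The deposited values named counts are a signal on a scaled axis and not raw counts, although raw counts had been assumed before the data were examined. In each tissue the low values of transcripts alone in their assembled gene were whole sums of 2 steps, one for each lane. Between 98.5% and 99.2% of these low values lay within 0.1% of such a sum. The steps were taken as the 2 smallest values shared by at least 50 such transcripts. An earlier rule, which took the 2 most frequent values, gave the same steps on the deposited data but failed on simulated data, in which the sum of both steps was sometimes more frequent, and it was replaced. Dividing by the steps gave an estimated 34929333 fragments for fat body, 34831295 for ovary, 27490311 for midgut and 36316835 for Malpighian tubules. The deposited FPKM carry the same scaling between tissues, so their sums differed: 935008 in fat body, 452542 in ovary, 1272696 in midgut and 603002 in Malpighian tubules. Rescaling each tissue to the same sum (TPM) over reference, intergenic and repeat-class loci moved log2 values by 0.12 in fat body, 1.17 in ovary, -0.32 in midgut and 0.79 in Malpighian tubules. Because no raw counts were at hand and each tissue had 1 library, no count model was fitted. In midgut 11 transcripts had a failed estimate and 13 too many fragments to be estimated, and 15 of these were listed at 0. In Malpighian tubules these numbers were 9, 1 and 3.

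Levels of 12340 reference genes were obtained by summing the FPKM of transcripts that match the annotated transcript, share a splice junction with it, overlap its exons on the same strand or lie in it as a single exon. The 2432 intergenic loci were sums over assembled transcripts outside the reference genes, taken by assembled gene, and 350 further loci lay in repeats. Of the intergenic transcripts, 52 belonged to an assembled gene that also held a reference gene. Transcripts on the opposite strand, inside introns, just past a gene end or with splice errors (671) were left out of the gene sums. The sources used here do not say whether strand was kept, so overlapping genes on opposite strands cannot be separated with confidence. Gene bounds are the sums of the bounds of their transcripts. A gene was detected at 1 FPKM or more. A gene was called tissue-enriched when its FPKM + 1 in a tissue was at least 5 times that in the next highest tissue, with at least 1 FPKM and 20 estimated fragments. For the 6 pairs of tissues, genes with a fold of at least 4 on the log2(FPKM + 1) scale were counted among those with 1 FPKM and 20 fragments in either tissue; this scale understates the change of low genes. An isoform was expressed at 1 FPKM and 10% of its gene. The main isoform differed between 2 tissues when the gene had at least 5 FPKM in both and a different isoform held at least 60% in each. Intervals for shares are 95% Wilson intervals and cover counting error only.

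The 16 gene lists fixed before the data were examined could not be used, because the reference table of 15394 genes contained 0 of the 12340 gene identifiers and the files do not pair these with names. By the rule fixed for that case, at most 2 identifiers are printed per direction: the 2 tissue-enriched genes with the highest FPKM per tissue and the 2 genes with the largest difference in isoform share. The intergenic loci named are the 3 with the highest FPKM and the next tissue-enriched one. Other transcripts and the gene named in the closing part were chosen after their values were seen.

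Computations used Python 3 with numpy, pandas, scipy and matplotlib. TMM and median-of-ratios factors were computed from their published rules. The rules were tested on simulated data for the 12340 genes, in which 50 genes were raised at each fold. Of these, 0 were called tissue-enriched at 3-fold, 96.0% at 8-fold and 100% at 16-fold and 32-fold, and 0 of 12140 unchanged genes were called. The simulation holds counting error only, so it checks that the rule was applied as written and says nothing of the spread between mosquitoes. Alternatives covered the thresholds, the pseudocount, the filter on low values, the scaling, the level of summary and the transcript classes. TPM for pairs of tissues, other definitions of a gene, leaving out the ovary library, subtracting a fraction of the ovary level, sums without the top 100 genes of each tissue and non-overlapping isoform bounds were chosen after seeing the data.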

Results

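The transcriptomes of fat body, ovary, midgut and Malpighian tubules of sugar-fed Anopheles stephensi females were compared to find tissue-restricted expression and alternative splicing. The fat body is the insect counterpart of liver and adipose tissue, the midgut digests the meal, and the Malpighian tubules are the excretory organs. Each tissue had 1 library of between 27490311 (midgut) and 36316835 (Malpighian tubules) estimated fragments. Differences between tissues therefore compare these libraries and have no replicate check. The FPKM bounds given below are those of the authors.

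At 1 FPKM or more, 8116 of the 12340 reference genes were detected in fat body, 7748 in ovary, 7284 in midgut and 7792 in Malpighian tubules. Of these genes, 6633 were detected in all 4 tissues, 777 in 3 and 564 in 2. A further 949 were detected in 1 tissue, 379 of them in fat body, 326 in ovary, 133 in Malpighian tubules and 111 in midgut. The order of tissues moved with scaling and threshold: with TPM the counts were 8314 in ovary, 8250 in Malpighian tubules, 8193 in fat body and 7082 in midgut, and at 5 FPKM ovary (6151) exceeded fat body (6030). With deposited values, the remaining 3417 genes stayed below 1 FPKM in every tissue. Expression was most concentrated in midgut, where 173 loci made up 50% of the fragments and the 10 most abundant loci held 13.2%. In fat body 212 loci were needed, in Malpighian tubules 418 and in ovary 489. The 10 most abundant loci held 6.36% of the ovary fragments.

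Tissue-enriched genes were sought to describe what sets each tissue apart. With the deposited FPKM, 424 genes were enriched in fat body, 244 in midgut, 181 in ovary and 144 in Malpighian tubules. The midgut genes carried 23.1% of all midgut fragments, and the fat body genes 17.6% of those of fat body. The Malpighian tubule genes carried 8.38% and the ovary genes 5.94% of the fragments of their tissue. The median level of enriched genes was 194 FPKM in midgut, 93.9 FPKM in fat body, 87.7 FPKM in Malpighian tubules and 29.3 FPKM in ovary. These medians were not taken with TPM, so their order holds for deposited FPKM only. The main isoforms of ovary-enriched genes had a median length of 2457 bases, against 1442 bases for fat body, 1572 bases for midgut and 1882 bases for Malpighian tubules. For the 7930 genes at 1 FPKM or more that were enriched in no tissue it was 1776 bases. These lengths are of the sets called with deposited FPKM. The place of ovary in the order of the counts depended on scaling and threshold. With TPM the counts were 729 in ovary, 342 in fat body, 213 in Malpighian tubules and 168 in midgut. With deposited FPKM, ovary came first at a ratio of 2 (1506 genes, against 874 in fat body) and last at a ratio of 10 (9 genes), and with a pseudocount of 0.1 FPKM it stood above midgut (415 against 292). A fraction of the ovary level was also subtracted from the other tissues, an alternative chosen after seeing the data. This subtraction can only raise the ovary count. Ovary then had 385 enriched genes and came second, after fat body (424) and before midgut (245). All 181 ovary genes, 340 of the fat body genes, 168 of the midgut genes and 143 of the Malpighian tubule genes were enriched under both scalings. For ovary this was fixed in advance, because its FPKM sum was the smallest and TPM raised it over every other tissue. Midgut had the largest sum, so TPM could only remove genes from its set.

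**Figure D1:**
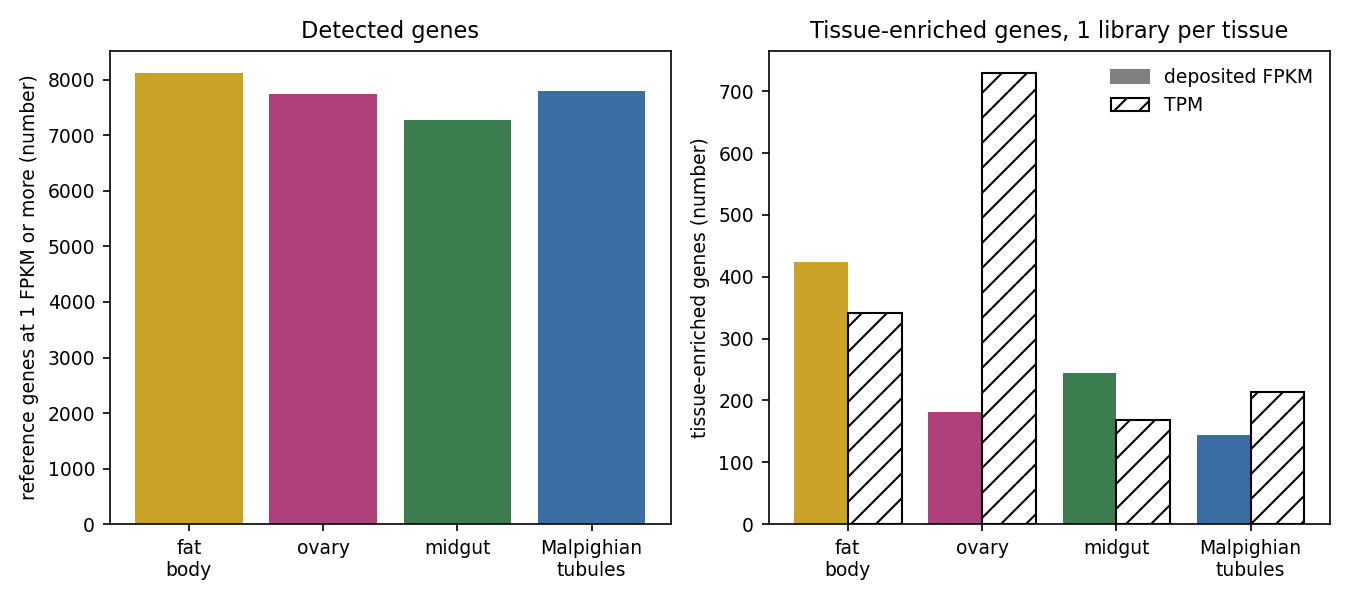
Numbers of reference genes in 4 tissues with 1 library each. The left panel shows genes at 1 FPKM or more, from 7284 in midgut to 8116 in fat body, and the right panel shows tissue-enriched genes with deposited FPKM (solid bars) and TPM (hatched bars), where the ovary count is 181 with deposited FPKM and 729 with TPM.

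The files do not pair gene identifiers with names, so the most abundant enriched genes are given by identifier and position. In midgut, ASTEI04993 (scaffold_00027, 571088 to 572030, plus strand, 2 exons) reached 51497 FPKM (bounds 48195 to 54799) and ASTEI01706 (scaffold_00006, 1225764 to 1227721, minus strand) reached 25212 FPKM (22066 to 28359). Their ratios to the next tissue were 104 and 51.6, and with TPM 76.7 and 24.0. In fat body, ASTEI02815 (scaffold_00011, 1367499 to 1368309, minus strand) stood at 6197 FPKM (6056 to 6338) and ASTEI07180 (scaffold_00050, 920138 to 921881, plus strand) at 4575 FPKM (4424 to 4727). Malpighian tubules had the next highest level of both, 109 FPKM and 81.1 FPKM, which gave ratios of 56.6 and 55.8, and with TPM 35.8 and 35.3. In Malpighian tubules, ASTEI04468 (scaffold_00023, 1051911 to 1052564, plus strand, 1 exon) reached 6028 FPKM (5659 to 6396) and ASTEI03825 (scaffold_00017, 2079964 to 2081569, minus strand) 4177 FPKM (4088 to 4266), with ratios of 38.1 and 20.4, and with TPM 60.4 and 43.9. An assembled transcript on the opposite strand covers ASTEI04468, and the sum over all classes naming this gene was 13883 FPKM, so its own level is uncertain.

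In ovary, ASTEI09319 (scaffold_00089, 9808 to 12360, plus strand, 4 exons) stood at 1760 FPKM (1711 to 1808) and ASTEI07089 (scaffold_00048, 1234782 to 1237446, minus strand, 3 exons) at 511 FPKM (469 to 552). Fat body was the next tissue for both, at 332 FPKM and 78.7 FPKM, which gave ratios of 5.28 and 6.42, and with TPM 10.95 and 13.3. The median level of the ovary-enriched genes was 12.6% of the ovary level in fat body, 8.58% in Malpighian tubules and 2.36% in midgut, and with TPM 6.07%, 6.57% and 0.837%. Midgut-enriched genes had a median of 4.25% of the midgut level in Malpighian tubules, and 9.16% with TPM. These TPM medians are of the genes called with deposited FPKM. They therefore cannot say which tissue's genes were the least restricted under TPM. Of 3116 genes with at least 2000 fragments in ovary, 7 lay below 5% of the ovary level in fat body and 6 in Malpighian tubules, against 190 in midgut. With TPM these numbers were 45, 14 and 414.

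**Figure D2:**
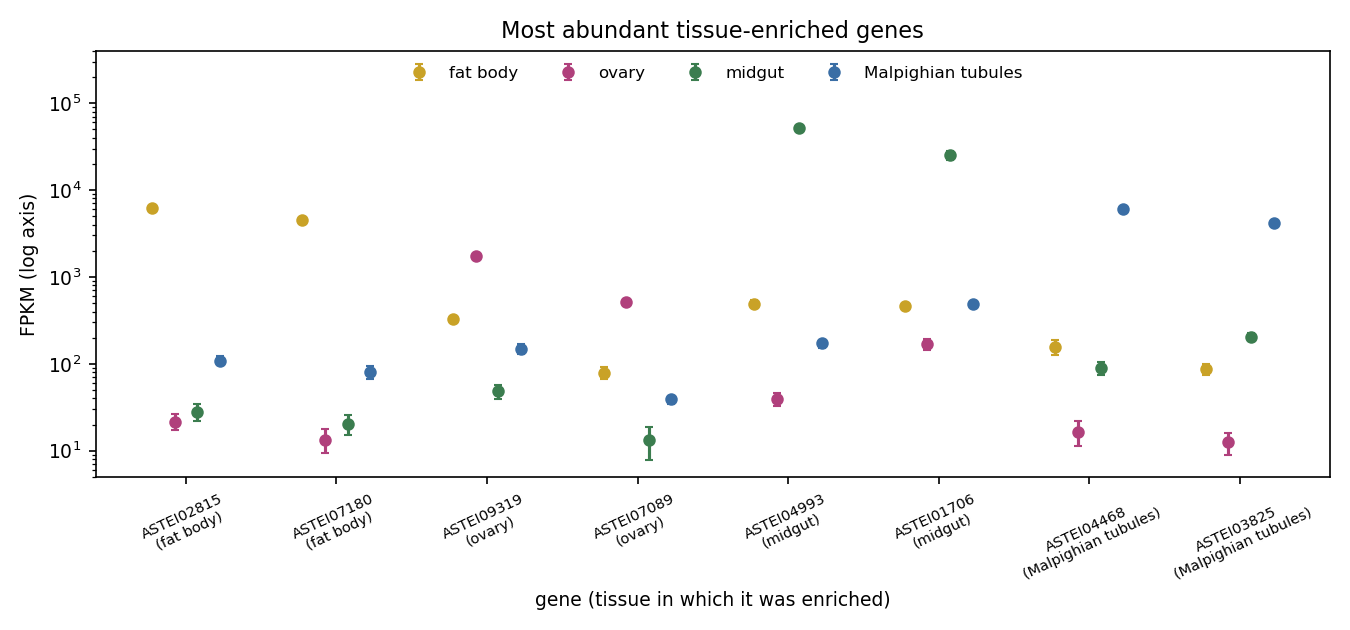
FPKM on a log axis of the 2 most abundant enriched genes of each tissue, with the authors' lower and upper bounds as bars and 1 library per tissue. The midgut genes reach 51497 and 25212 FPKM, and the ovary genes, at 1760 and 511 FPKM, have the smallest ratios to the next tissue, 5.28 and 6.42 (10.95 and 13.3 with TPM).

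By rank correlation, midgut and Malpighian tubules were closest together and the 3 pairs with ovary had the lowest values. Across 8923 genes at 1 FPKM or more in any tissue, Spearman's correlation was 0.844 between midgut and Malpighian tubules and 0.783 between fat body and Malpighian tubules. It was 0.712 between fat body and midgut, 0.662 between ovary and Malpighian tubules, 0.633 between fat body and ovary, and 0.613 between ovary and midgut. These correlations are across genes, which are not independent replicates. With a fold of 4 or more, 943 genes differed between midgut and Malpighian tubules, 419 of them higher in midgut and 524 in Malpighian tubules. Between ovary and midgut 2275 genes differed, 1093 higher in ovary and 1182 in midgut. The other pairs differed in 1696 genes (fat body and ovary), 1719 (ovary and Malpighian tubules), 1556 (fat body and midgut) and 1151 (fat body and Malpighian tubules). The pair with the fewest differing genes depended on scaling: with TPM it was fat body and Malpighian tubules (1357), ahead of midgut and Malpighian tubules (1491).

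The split of these differences moved by over 10 percentage points with scaling in every pair, and the tissue with more of the higher genes changed in 4 of the 6 pairs. Between fat body and ovary, 1184 genes were higher in fat body and 512 in ovary with deposited FPKM, but 778 and 2114 with TPM. Between ovary and midgut, TPM gave 3037 genes higher in ovary and 587 in midgut. Between ovary and Malpighian tubules, 675 and 1044 became 1334 and 929. Between midgut and Malpighian tubules, TPM gave 244 and 1247. In the pairs of fat body and midgut and of midgut and Malpighian tubules, the same tissue had more of the higher genes under both scalings. Between fat body and midgut, 912 and 644 became 1089 and 493, and between fat body and Malpighian tubules, 679 and 472 became 532 and 825.

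Intergenic loci outside the reference genes were also expressed. Of 2432 such loci, 2237 reached 1 FPKM in any tissue, 70.5% of them with a single exon, and with deposited FPKM the highest level was in ovary for 747, in Malpighian tubules for 526, in midgut for 516 and in fat body for 448. ANSTF.1393 (scaffold_00005, 2488549 to 2491391, 1 exon) was abundant everywhere, at 7577 FPKM (6888 to 8265) in midgut, 4495 FPKM in fat body, 3383 FPKM in Malpighian tubules and 606 FPKM in ovary. Its ratio of midgut to the next tissue was 1.69, against fat body, and 1.04 with TPM, against Malpighian tubules. ANSTF.5135 (scaffold_00031, 1038032 to 1038809, 3 exons) was likewise expressed in all tissues, from 1504 FPKM in Malpighian tubules to 5301 FPKM in midgut, and with TPM its highest level was in ovary. ANSTF.1096 (scaffold_00004, 3194804 to 3195385, 2 exons) was enriched in fat body at 7411 FPKM (7277 to 7544), against 1089 FPKM in midgut and 1006 FPKM in Malpighian tubules. Its ratio to the next tissue was 6.80 and fell to 4.64 with TPM, against Malpighian tubules, so that it was no longer enriched. ANSTF.2654 (scaffold_00011, 1365001 to 1366080, 4 exons) was enriched in fat body at 4247 FPKM (4019 to 4475), with 87.8 FPKM in Malpighian tubules and a ratio of 47.8 (30.3 with TPM). It lies on the same scaffold and strand as ASTEI02815 and had a similar profile.

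Of the expressed intergenic loci, 175 (7.82%, 95% Wilson interval 6.78 to 9.01) were tissue-enriched, compared with 993 of 8923 reference genes (11.1%, 10.5 to 11.8). Expressed loci in repeats were enriched in 5 of 291 cases (1.72%, 0.736 to 3.96), but the rule cannot call a locus below 4 FPKM, and only 102 of the 291 reached that level, against 7846 of the 8923 reference genes. Reference genes drawn to match the intergenic loci in mean FPKM were enriched in 6.99% of cases (5.99 to 8.05 over 1000 draws), a range that includes the share of the intergenic loci. Among loci with 2 or more exons, 12.1% of 660 intergenic loci (9.85 to 14.8) and 11.1% of 8319 reference genes (10.5 to 11.8) were enriched, and these intervals overlap.

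Alternative isoforms were common in all tissues. Ovary had 2995 genes with 2 or more expressed isoforms (39.2% of its genes with an expressed isoform), Malpighian tubules 2735 (35.7%), fat body 2722 (34.0%) and midgut 2504 (35.0%). The main isoform differed between tissues in 257 genes. These made 503 combinations of a gene and a pair of tissues. In 394 of them (78.3%) the 2 isoforms carried different labels for the transcription start. These labels belong to annotated or assembled transcript models, and the starts themselves were not measured. How often any 2 isoforms of a gene differ in this label was not counted. Whether 78.3% is high therefore cannot be told. The share of genes compared was highest between ovary and midgut (111 of 2803 genes, 3.96%, 95% Wilson interval 3.30 to 4.75) and lowest between fat body and Malpighian tubules (50 of 3125, 1.60%, 1.22 to 2.10). The count of 257 genes depended on the thresholds: it was 709 at a share of 50%, 45 at a share of 80% and 97 at 20 FPKM per gene, and 220 with non-overlapping FPKM bounds for the main isoform.

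For ASTEI00261 (scaffold_00001, minus strand), ANSTF.239.3 held 91.1% of the gene level in ovary, at 14.9 FPKM (12.2 to 17.5), and was listed at 0 in midgut. ANSTF.239.2 held 98.4% in midgut, at 7.97 FPKM (6.89 to 9.04), 80.8% in Malpighian tubules and 74.0% in fat body. Both have 11 exons, and ANSTF.239.3 begins at 4012432 and ANSTF.239.2 at 4012130. For ASTEI07282 (scaffold_00051, minus strand), ANSTF.6737.7 (868748 to 879927, 6 exons) was the only isoform above 0 in Malpighian tubules, at 45.3 FPKM (40.3 to 50.2). The annotated isoform (865395 to 871302, 7 exons) held 98.1% in ovary, 97.9% in midgut and 93.1% in fat body, and was listed at 0 in Malpighian tubules. The spans of these isoforms overlap only between 868748 and 871302. In the whole annotation, 706 assembled genes held several reference genes. Whether ANSTF.6737.7 is an isoform of ASTEI07282 or a transcript of a neighbouring unit was not tested.

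**Figure D3:**
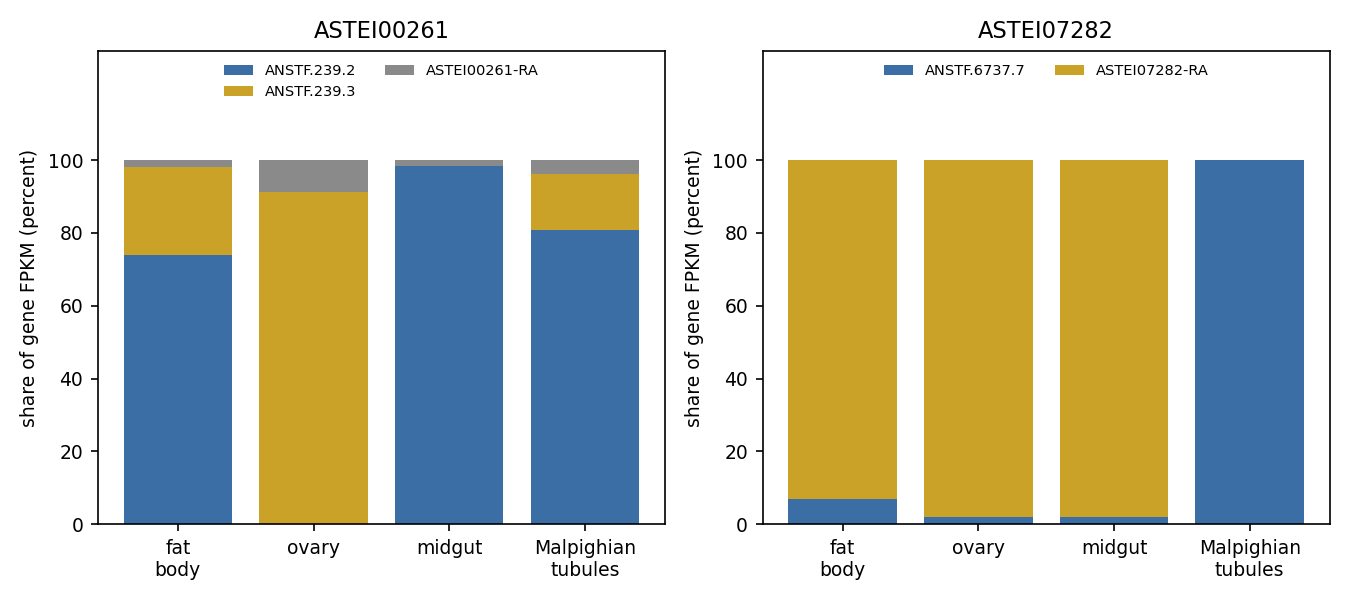
Share of gene FPKM, in percent, held by each isoform of ASTEI00261 (left) and ASTEI07282 (right) in the 4 tissues, 1 library each, as stacked bars. ANSTF.239.3 holds 91.1% of ASTEI00261 in ovary and 0% in midgut, and ANSTF.6737.7 holds 100% of ASTEI07282 in Malpighian tubules. The span of ANSTF.6737.7 overlaps that of the annotated isoform only in part.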

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

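All tests in this part but that on intergenic loci, whose limits were set before its values were seen, were chosen after the result was seen.

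Signal appeared in transcripts that the main comparisons left out. Only the alternative that summed all classes naming a gene used some of them. At 1 FPKM or more in any tissue there were 248 transcripts on the strand opposite to a reference gene, 72 inside introns and 307 just past the end of a gene. The most abundant of the opposite-strand transcripts, ANSTF.4175.1 (scaffold_00023, 1051638 to 1052564), reached 7855 FPKM in Malpighian tubules and covers ASTEI04468. The most abundant intronic one, ANSTF.7396.1 (scaffold_00061, 488287 to 490201), reached 5767 FPKM in midgut.

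The authors' deposited list of alternative transcripts gave ANSTF.3986.3, an isoform of ASTEI04270, 5589 FPKM in fat body, and the FPKM table gave it 8.68 FPKM. The only entries that differed between the lists and the table were 5 isoforms of this gene. In fat body these 5 summed to 5646 FPKM in the list and 729 FPKM in the table, where the whole gene had 2804 FPKM. The calls above used the table, in which this gene was not enriched. Which values are right is not known. Whether the gene is fat body-enriched, and which enriched genes are the most abundant there, depends on this.

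Genes abundant in ovary rarely fell to low levels in fat body and Malpighian tubules. Ovary RNA in both libraries would bring intergenic loci along too: of 340 with at least 500 fragments in ovary, at most 1.76% (95% Wilson interval 0.811 to 3.80, fat body with TPM) lay below 3% of the ovary level in either tissue, against 17.6% in midgut with TPM. That interval includes the limit of 2%, so this explanation stays open. Subtracting 6.95% of the ovary level from fat body, 6.40% from Malpighian tubules and 0.829% from midgut gave 385 ovary-enriched genes in place of 181. Such a subtraction can only raise this count, so the rise does not bear on the explanation. Fragments exchanged in both directions are argued against, since the 1st percentile of the fraction was at least 9.93 times higher for ovary genes in these tissues than for their genes in ovary, under both scalings. Over the 3116 genes with at least 2000 fragments in ovary, the fraction of the ovary level had a log2 interquartile range of up to 2.09. That range covers all of these genes, with a median fraction of 66.7% in both tissues, and does not describe the low ones. For 200 of them chosen for low levels in midgut, the median fraction was 15.4% in fat body and 9.31% in Malpighian tubules. Their log2 interquartile ranges were narrower, 0.872 and 1.07. Expression in the tissues themselves cannot be told apart from ovary RNA with 1 library each.

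The number of ovary-enriched genes was 181 with deposited FPKM and 729 with TPM. A few abundant genes are argued against as the cause, because leaving the top 100 genes of each tissue (230 loci) out of the sums still gave 728. Leaving out the loci of highest mean gave 812 genes without 100 loci, 398 without 500, 267 without 1000, 152 without 2000 and 108 without 3000. The 1000 loci of highest mean held 79.3% of the FPKM. On deposited FPKM the median-of-ratios factors were 0.911 to 0.999 and the TMM factors 0.969 to 1.04. These scalings gave 162 and 182 ovary-enriched genes. The deposited scaling thus follows the typical gene, whereas the TPM factors, 0.444 in ovary and 1.25 in midgut, follow the sums. The gap between 181 and 729 lies between these kinds of scaling. As loci were left out, the count fell past 181 without settling, so which loci account for the gap stays open. A real difference in RNA content between tissues was not tested and stays open.

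Neighbouring genes were often enriched in the same tissue with deposited FPKM, and pairs were not counted with TPM. There were 102 such pairs, and the highest of 1000 shuffles of the calls among expressed genes gave 41; without pairs that overlap or share an assembled gene there were 79, against at most 34. Transcription running on into the next gene is argued against as the whole cause, because 18 of the pairs lay head to head without overlap, where transcription runs apart on either strand. The margin is narrow, since the highest of the shuffles gave 17 (mean 6.79). For the 102 pairs, reads shared between similar copies cannot be told apart from regional expression, because no genome sequence was compared.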

How the results depend on the processing

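Of 148 alternative values, 100 stayed within their limit (1.5 times for a count, the 95% interval otherwise) and 48 moved. Some had little room to move. On deposited FPKM the median-of-ratios factors were 0.911 to 0.999 and the TMM factors 0.969 to 1.04. The rule for enriched genes already needs 4 FPKM, so dropping its limit of 1 FPKM could change little. All 20 counts of detected genes stayed within 1.5 times, though their order changed, and all 40 alternative ratios of the 8 named genes stayed at 5 or more, although TPM moved 7 of them by over 1.5 times. Alternatives added after seeing the data are TPM for pairs, the ovary subtraction, sums without the top genes, other gene definitions, the ovary left out and non-overlapping bounds. The cause of a move was not tested unless named. No paired analysis was possible because each tissue has 1 library, which also rules out leaving out replicates. The 3 gene list alternatives were not run, as no identifier has a name.

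Stricter or looser limits change counts by construction. Enriched genes at a ratio of 2 were 874 in fat body, 1506 in ovary, 651 in midgut and 406 in Malpighian tubules, and at a ratio of 10 they were 263, 9, 155 and 75. At transcript level they were 662, 384, 462 and 292. In ovary alone, the count was 415 with a pseudocount of 0.1 FPKM, 729 with TPM, 728 with sums without the top 100 genes and 385 with the ovary fraction subtracted; it stayed within 1.5 times with TMM and median of ratios. At a fold of 2, pairs gave 4526 (fat body and ovary), 3168 (fat body and midgut), 2653 (fat body and Malpighian tubules), 4709 (ovary and midgut), 4514 (ovary and Malpighian tubules) and 2534 (midgut and Malpighian tubules). With TPM, 3 pairs moved: 2892 (fat body and ovary), 3624 (ovary and midgut) and 1491 (midgut and Malpighian tubules), the last above the 1357 of fat body and Malpighian tubules.

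Rank correlations, in the same order of pairs, were 0.832, 0.861, 0.899, 0.819, 0.848 and 0.919 over all genes, where unexpressed genes are added, and 0.565, 0.636, 0.725, 0.518, 0.569 and 0.782 at transcript level. The share of enriched reference genes was 6.99% when matched to intergenic loci on mean FPKM, and that of intergenic loci with 2 or more exons 12.1%, with an interval that includes the 11.1% of reference genes. Genes with 2 or more isoforms numbered 1805 in fat body and 1763 in Malpighian tubules at a share of 25%, and 1423, 1513, 1431 and 1463 (fat body, ovary, midgut, Malpighian tubules) at 5 FPKM per isoform. Main isoforms differed in 709 genes at a share of 50%, 45 at 80% and 97 at 20 FPKM per gene. Depth limits genes near 1 FPKM; midgut is the shallowest library, and thinning the others to it, a small step, gave 8111 detected genes in fat body, 7747 in ovary and 7797 in Malpighian tubules.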

Other observations

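All tests in this part were chosen after the result was seen.

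Enriched genes formed runs along the scaffolds, overlapping genes included. With deposited FPKM, 14 runs held 3 or more neighbouring genes enriched in the same tissue, against at most 4 in the shuffles. Of the 14 runs, 9 lay in fat body, 4 in midgut, 1 in Malpighian tubules and 0 in ovary. The sets of enriched genes differed in size, with 424, 244, 144 and 181 genes in the same order. The shuffles were not split by tissue, so whether this split goes beyond the set sizes cannot be told. Runs were not counted with TPM, so their number and split by tissue hold for deposited FPKM only. The longest run held 5 fat body genes between 1732854 and 1741833 on scaffold_00005, with 58.9 to 140 FPKM. On scaffold_00042, 4 midgut genes between 1507665 and 1525515 (74.7 to 904 FPKM) were followed directly by 4 fat body genes between 1525706 and 1559296 (80.7 to 887 FPKM). The midgut gene with 74.7 FPKM (1520178 to 1521779) lies inside another of the run (1520128 to 1525515), both on the minus strand. Whether these are separate units was not tested. With TPM not every gene of either run reaches the ratio of 5, so neither run of 4 holds there. On scaffold_00121, 3 midgut genes between 315302 and 325897 all had 4473 to 5978 FPKM. In Malpighian tubules, 3 genes between 951237 and 1052564 on scaffold_00023 had 2153 to 6028 FPKM. The highest of these values is that of ASTEI04468, whose own level is uncertain because a transcript on the opposite strand covers it.

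Intergenic loci may be unannotated ends of the nearest expressed gene. Among loci with at least 5 FPKM, 44.2% (129 of 292) within 2000 bases of that gene had their highest level in the same tissue, 46.2% (49 of 106) at 2000 to 10000 bases and 31.2% (24 of 77) beyond. The difference between the nearest and the farthest class was 13.0 percentage points (95% interval 1.2 to 24.8), and the share did not fall from the nearest to the middle class, so these data leave the hypothesis open.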
